A study of Drosophila melanogaster and Nicrophorus vespilloides with 16 samples.

How the data were processed

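H3K4me3 ChIP-seq was measured in 8 libraries, 4 from whole third-instar larvae of Drosophila melanogaster (30 larvae per replicate) and 4 from adult brains of Nicrophorus vespilloides (1 brain per replicate). The labels call these biological replicates, and 8 matching input libraries were not analysed here. Per the labels' protocols, tissue was fixed in 1% formaldehyde for 10 min, chromatin was sonicated for 10 min in total (fly) or 8 min (beetle), and 30 µg of chromatin went into each immunoprecipitation on a solid-state filter. Per the submitters' processing notes the tools were FastQC 0.11.7, cutadapt 1.16, BWA 0.7.17, SAMtools 1.9, Picard 2.17.11 and MACS2. The MACS2 version, its parameters, the treatment of duplicates, the genome builds and the use of the input are not given in the sources used here.

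Each deposited list holds the summits called in 1 sample, so the replicates were not pooled by the authors. The score that the authors deposited with each summit has the form of a −log10 p-value or q-value as MACS2 writes it, and which of them it is was not stated. The smallest fly scores, 1.31 to 1.36, lie just above 1.301, the value at a threshold of 0.05. A score depends on sequencing depth and is not scaled between libraries. It was therefore used to rank or filter summits within a sample or to correlate ranks, genes and regions were ordered by the mean of their percentiles within each sample, and scores of different samples are given side by side as values only. Read depth is unknown, so fewer summits in a sample can reflect fewer reads, and no counting interval was computed.

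Gene names, gene ends and gene types came from a RefSeq gene table of Drosophila melanogaster (Release 6 plus ISO1 MT). No label names the build of the fly positions, so it was checked on the data. With each arm matched to its own genes, 57.1% to 88.0% of summits lay within 500 bp of a gene end, against at most 19.6% with the genes of any other arm and at most 28.8% after a shift of 10 kb. Positions are the summits as deposited, written 1-based. The table has no strand, transcripts or sequence, and this changed the plan: a distance to a transcription start site became a distance to either end of a protein-coding gene, the signed position relative to the start became the position inside or outside the gene of the nearest end, and promoter motifs were not run. Exons, introns and untranslated regions were not used here.

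Summits of different fly replicates at most 250 bp apart counted as shared, and summits chained at that distance formed regions. A gene was called marked when a summit lay within 1 kb of either end in at least 3 of 4 replicates. Random expectations came from 100 placements of each replicate's summits on the same chromosome. Before the data were examined, 32 gene lists were fixed, and 31 were tested. The list of fertility genes on Y was left out, since genes on Y were not searched for summits. Only 4 listed symbols were unmatched (calypso, Trh, phm and Dpt). Each list with at least 5 genes was compared with all other protein-coding genes on the 6 arms by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over lists and a threshold of 0.05. Chromosome arms were tested in the same way, adjusted over arms. The numbers of summits in the 2 species were compared by an exact permutation test, two-sided.

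Genes were named by a rule fixed before the data were examined. It takes the 10 genes with the highest mean score percentile among those with a summit in all 4 replicates, where a gene's score is that of its highest summit within 1 kb and absence counts as 0. For each list past the threshold it takes the marked member with the highest percentile and the alphabetically first member with no summit. For the other tested lists it takes the marked member with the highest percentile. All members of the H3K4 methylation list and all beetle summits are named too. Neighbouring genes that hold a summit, Cp110 and the genes named in the closing section outside this rule were chosen after their values were seen.

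Alternatives were scores of at least 5, equal numbers of summits per replicate, each replicate left out in turn, other distances for shared summits and gene ends, other numbers of replicates, isolated genes, log10 of the number of summits, and a replicate block for the species. With a fly replicate left out, a summit in at least 2 of the remaining replicates was asked for. A search of the whole gene span, summits inside the gene and lists matched on gene length were added after seeing the data. The steps were tested on simulated summits planted at 2500 of 13922 genes. They marked 95.4% of the planted genes, where 94.8% was expected, and 13.5% of the other genes through neighbouring ends, and called 0 of 40 lists drawn at random. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.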

Results

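Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out in 2 insects with an antibody against trimethylation of lysine 4 of histone H3 (H3K4me3), a histone mark found at the starts of active genes. The chromatin was captured on a solid-state filter (Chromatrap) instead of beads, and per the labels the work was set up to adapt the protocol to insect tissue. The fly samples were 4 replicates of 30 whole third-instar larvae each, of the Oregon-R strain of Drosophila melanogaster. The beetle samples were 4 replicates of 1 adult brain each, from the burying beetle Nicrophorus vespilloides. Each of the 8 ChIP libraries came with a list of peak summits, each summit being the 1 bp position of highest enrichment within a called peak, with the authors' score. The 8 input libraries were not analysed here, and the read depth of every library is unknown, so the number of summits is the only measure of yield per sample.

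The fly larvae gave a large number of H3K4me3 summits and the beetle brains gave very few. Fly replicates 1 to 4 held 3518, 4969, 5236 and 5313 summits, a mean of 4759 ± 840 (SD, n = 4). Beetle replicates 1 to 4 held 2, 1, 1 and 3 summits, a mean of 1.75 ± 0.957 (SD, n = 4). The smallest fly replicate held 1173 times as many summits as the largest beetle replicate, so the difference was larger than the spread within either species. An exact permutation test of the difference in means, two-sided, gave p = 0.0286, the smallest value that 70 splits of 4 against 4 samples allow, and leaving out any 1 library gave an exact permutation p = 0.0571, the smallest possible at that size. Species, tissue, life stage, number of animals and sonication time (10 min in the fly, 8 min in the beetle) all differed together, so the comparison is between 2 preparations and not between 2 species alone.

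**Figure D1:**
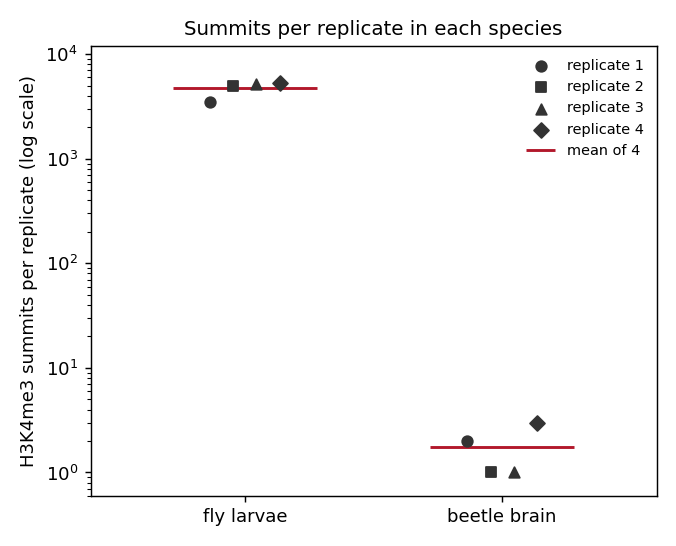
Number of H3K4me3 summits in each of 4 fly and 4 beetle replicates (points, logarithmic vertical axis), with the mean of each species as a line. The fly replicates lie between 3518 and 5313 summits and the beetle replicates between 1 and 3.

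A single site of the beetle genome accounted for the summits found in all 4 brains. It lies on scaffold NW_017097073.1, at positions 16648, 16654, 16635 and 16646 in replicates 1 to 4, a span of 19 bp. Its scores were 146, 61.6, 10.2 and 69.2 in replicates 1 to 4. The other 3 beetle summits were each present in 1 replicate. They lie on NW_017099416.1 at position 2188 in replicate 1 (score 7.41), on NW_017097136.1 at 15514 in replicate 4 (score 7.15) and on NW_017099019.1 at 25009 in replicate 4 (score 5.44). The genes near these summits were not analysed here.

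The second question was how well the 4 fly replicates repeat each other. On average 73.2% ± 5.47 (SD, n = 4) of a replicate's summits lay within 250 bp of a summit of another replicate, against 1.76% for summits placed at random on the same chromosomes. Joining summits at most 250 bp apart gave 7031 regions, of which 2433 held a summit from 4 replicates, 1793 from 3, 1032 from 2 and 1773 from 1. The 4226 regions present in at least 3 replicates had a median width of 101 bp, and random placement gave a mean of 8.51 such regions. None of 100 random placements came as high for either measure (permutation p = 0.0099, the smallest that 100 placements can give). Fly replicate 1, with the fewest summits, had the highest share found in others, 80.8%, and replicate 4, with the most, the lowest, 67.8%, but this share depends on the lengths of the lists compared.

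The scores agreed less well than the positions. The median score was 5.97, 8.83, 15.2 and 24.7 in fly replicates 1 to 4. Across regions shared by a pair of replicates, Spearman's rho of the scores had a mean of 0.351 ± 0.134 (SD over 6 pairs). It ran from 0.209 between replicates 1 and 2 to 0.564 between replicates 3 and 4. These are correlations across regions, which are not independent replicates, so no p-value is given. No position and score were the same in any pair of files, so no library appeared to have been deposited more than once.

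The fly summits lay at the ends of protein-coding genes. Of the summits of a replicate, 95.0% ± 2.18 (SD, n = 4) were within 1 kb of an annotated end of such a gene, against 24.7% at random (permutation p = 0.0099, the smallest that 100 placements can give). The gene of the nearest end held the summit in 94.2% ± 0.285 of cases (SD, n = 4), against 58.1% at random, and the median summit lay 209 ± 13.7 bp inside the gene. Long isolated genes, at least 5 kb in length and with no other gene end within 2 kb, allow the ends to be told apart: of 521 such genes, 62 had a summit at 1 end, 0 at both ends and 459 at neither. Summits near gene ends had a median score 2.22 ± 0.937 times that of the other summits (SD, n = 4), with ratios of 1.29, 1.64, 2.57 and 3.37 in replicates 1 to 4. The gene table used here carries no strand, so starts and 3' ends were not separated, and with equal numbers of summits per replicate the score ratio was 1.20.

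By this measure 6107 of 13922 protein-coding genes (43.9%) were marked, meaning that a summit lay within 1 kb of either end in at least 3 of the 4 fly replicates. Of all these genes, 4693 had a summit in 4 replicates, 1414 in 3, 443 in 2, 420 in 1 and 6952 in none. Random placement marked a mean of 91.7 genes (permutation p = 0.0099, the smallest that 100 placements can give). Because fly genes lie close together, a summit often fell within 1 kb of several genes, and asking for a summit inside the gene itself left 4329 marked genes. With a window of 250 bp the number was 2628.

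Several of the strongest sites were shared by neighbouring genes, as were most summits. Of all summits of a replicate, 76.7% ± 4.08 (SD, n = 4) lay within 1 kb of at least 2 protein-coding genes. The highest mean score percentile among the summits of each replicate, 98.9 ± 1.03 (SD, n = 4), belonged to a summit shared by Su(P) and CG4101 on chromosome 3L at position 16612017 in replicate 4, where it lay inside Su(P). Next came senju on 2L at 98.6 ± 0.761. Its strongest summit was at position 5052657 in replicate 1 and at 5055362 in replicate 4, and the latter lies inside the neighbouring His3.3A, which encodes the replacement histone H3.3. ZIPIC, a zinc-finger protein that binds insulator sites, and its neighbour ocn, a gene of the testis-expressed janus family, shared a summit at 3R position 30036690 in replicate 4, inside ZIPIC, with a percentile of 98.3 ± 1.163. Prosbeta7, a subunit of the proteasome core, reached 98.2 ± 2.03 with a summit inside the gene at 3R position 5357978 in replicate 4. IPIP had 98.1 ± 1.54 and CG5504 had 98.1 ± 2.51. The strongest IPIP summit of replicate 4 lay inside CG9135, and that of CG5504 lay where CG5504 and Alg3 overlap, with a score of 82.8. CG12848 and CG3880 shared the last of the 10 places at 97.9 ± 1.83, with the replicate 4 summit inside CG3894.

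Genes of protein synthesis, protein breakdown and respiration were marked more often than other genes, the listed ribosomal and proteasome genes almost throughout. All 73 genes of mitochondrial ribosomal proteins were marked, against 43.6% of the other genes (adjusted p = 1.82e-25, Fisher's exact test), and the share with a summit was 95.9% ± 6.43 per replicate (SD, n = 4). Of 76 genes of cytoplasmic ribosomal proteins 75 were marked (adjusted p = 7.50e-25, Fisher's exact test), with 96.4% ± 4.61 per replicate. The strongest was RpLP2, a protein of the ribosomal stalk, at a score percentile of 94.3 ± 6.59 (SD, n = 4), and RpS10a had no summit in any replicate. The proteasome list had 30 of 32 genes marked (adjusted p = 1.29e-08, Fisher's exact test), led by Prosbeta7, and Prosalpha1 had no summit. Grouping by symbol stem, chosen after the main results had been seen, gave lower shares. Of all genes with the stem Prosalpha 6 of 12 were marked, and with Prosbeta 8 of 13, neither past the threshold. Only 7 genes of each stem were in a fixed list. The respiratory chain and ATP synthase had 60 of 74 (adjusted p = 3.93e-10, Fisher's exact test) and the translation factors 43 of 52 (adjusted p = 3.54e-08, Fisher's exact test). UQCR-C2, a core subunit of respiratory complex III, stood at 97.52 ± 0.890, and ATPsynCF6L had no summit. The strongest replicate 4 summit near UQCR-C2 lay inside Rpn12, but UQCR-C2 also had a summit inside the gene itself in at least 3 replicates. eIF2Bdelta, a subunit of the exchange factor for eIF2, stood at 91.5 ± 2.35 with its replicate 4 summit inside roh, and eIF3d2 had none. mRpL23 led the mitochondrial ribosome at 96.6 ± 3.82, with its replicate 4 summit inside CG9004.

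Chromatin regulators were also marked more often than other genes. Of 24 genes of the Polycomb and Trithorax groups, which keep developmental genes silent or active, 20 were marked (adjusted p = 0.000246, Fisher's exact test), with 77.1% ± 7.98 per replicate (SD, n = 4). phol, a DNA-binding Polycomb group protein, had the highest percentile, 93.7 ± 12.3, and a replicate 4 summit inside the gene with a score of 74.6. ph-p, a core component of Polycomb repressive complex 1, had no summit near an end but was marked when the whole gene was searched. This list lost its call when a summit in all 4 replicates was asked for (adjusted p = 0.0663, Fisher's exact test) and with a window of 250 bp (adjusted p = 0.0585, Fisher's exact test).

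Genes of the H3K4 methylation machinery, which holds methyltransferases, demethylases and their partner subunits, were also marked more often than other genes. Of 16 such genes 14 were marked (adjusted p = 0.000867, Fisher's exact test), with 89.1% ± 10.7 per replicate (SD, n = 4). The highest score percentiles were those of Dpy-30L1 (94.1 ± 4.23), Ptip (91.9 ± 9.10) and trr (83.6 ± 10.2), the last encoding a methyltransferase of the COMPASS-like complexes. Wdr82 had 77.6 ± 25.3, Ncoa6 had 72.6 ± 27.6, the demethylase Kdm5 had 71.7 ± 21.6 and Mnn1 had 67.9 ± 27.1. The shared core subunits wds, ash2 and Rbbp5 had 62.4 ± 15.9, 62.1 ± 6.67 and 59.2 ± 12.3. The H3K27 demethylase Utx had 59.2 ± 25.3 and Cfp1 had 50.2 ± 10.96. Set1, the main H3K4 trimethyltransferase of the fly, and Hcf had a summit near an end in 3 replicates, at 38.5 ± 36.8 and 28.02 ± 25.8 with absence counted as 0. Set1 also held a region more than 1 kb from gene ends in 4 replicates (3L, 25109251 to 25109438, 51.9 ± 33.5). The 2 genes not marked were Su(var)3-3, the fly LSD1 demethylase, with a summit in 2 replicates, and trx, a founding Trithorax gene, with a summit in 1 replicate. The strongest replicate 4 summits near Cfp1, Mnn1, Ncoa6, Rbbp5, Set1, ash2 and wds lay inside a neighbouring gene. Of these, Cfp1, Mnn1, Ncoa6, Rbbp5 and wds also had a summit inside the gene itself, within 1 kb of an end, in at least 3 replicates. Set1 and ash2 did not.

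In 16 lists, genes were marked less often than other genes. The samples were whole larvae, and expression was not analysed here. A low share thus does not show that these genes were inactive in their own tissues. Cuticle proteins had 3 of 117 genes marked (adjusted p = 5.79e-24, Fisher's exact test). The chemoreceptors followed, with 2 of 59 odorant receptors (adjusted p = 2.40e-11, Fisher's exact test), 4 of 60 gustatory receptors (adjusted p = 1.11e-09, Fisher's exact test) and 7 of 60 ionotropic receptors (adjusted p = 3.74e-07, Fisher's exact test). Ccp84Aa, Or10a, Gr10a and Ir100a had no summit. The marked member with the highest percentile in each of these lists had its replicate 4 summit inside a neighbour: Lcp9 (90.6 ± 5.38) in CG3594, Or85f (81.1 ± 14.5) in CG34117, Gr97a (75.4 ± 16.2) in CG5521 and Ir8a (85.1 ± 10.1) in CG12121.

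Reproductive genes were mostly without summits in these larvae. Accessory gland proteins had 3 of 49 genes marked (adjusted p = 2.40e-08, Fisher's exact test) and testis and spermatid genes 2 of 35 (adjusted p = 2.83e-06, Fisher's exact test). Acp98AB (62.4 ± 16.4) and mia (70.8 ± 37.5) led these lists through summits inside HSPBAP1 and CG2519, and Acp24A4 and aly had none. Accessory gland genes are short, with a median length of 480 bp, and lists matched on gene length had a share of 22.5%. The difference was −16.4 percentage points against matched lists and −37.9 against all other genes. For testis and spermatid genes it was −36.7 against matched lists and −38.2 against all other genes. Chorion, vitelline membrane and yolk genes had 2 of 20 marked (adjusted p = 0.00385, Fisher's exact test). Both marked members, Cp190 (83.5 ± 10.2) and Cp110, entered that list by their symbols and are centrosome and insulator proteins, not eggshell proteins, and Cp15, a chorion protein, had no summit.

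Lists of salivary gland, immune, tracheal, midgut, neuronal, muscle and photoreceptor genes were also marked less often. No gene was marked among 22 salivary glue and Eig71E genes (adjusted p = 8.74e-06, Fisher's exact test), 14 antimicrobial peptides (adjusted p = 0.000867, Fisher's exact test) and 7 tracheal genes (adjusted p = 0.0278, Fisher's exact test). Eig71Ea, AttA and bnl are members of these lists with no summit in any replicate. With lists matched on gene length the expected share was 24.8% for glue and Eig71E genes, 23.0% for antimicrobial peptides and 40.3% for tracheal genes. Against matched lists the glue and Eig71E genes kept their call, and the antimicrobial peptides and tracheal genes lost theirs. Midgut serine proteases had 3 of 27 genes marked (adjusted p = 0.000668, Fisher's exact test), neuronal genes 2 of 24 (adjusted p = 0.000544, Fisher's exact test), muscle sarcomere genes 3 of 22 (adjusted p = 0.00622, Fisher's exact test) and phototransduction genes 2 of 17 (adjusted p = 0.00938, Fisher's exact test). Tm1, a tropomyosin gene, stood at 70.7 ± 35.3 with its replicate 4 summit where Tm1 and l(3)neo43 overlap. Jon65Ai (50.1 ± 35.5), the acetylcholine receptor subunit nAChRalpha6 (58.5 ± 28.1) and the rhodopsin Rh4 (86.5 ± 6.04) had theirs inside tant, CG13123 and CG9951. alphaTry, Ace, Act57B and Arr1 had none.

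Developmental transcription factors and signals were also less often marked. Hox and segmentation genes had 2 of 25 marked (adjusted p = 0.000337, Fisher's exact test) and imaginal disc patterning genes 4 of 26 (adjusted p = 0.00424, Fisher's exact test). The share with a summit rose from replicate 1 to 4, from 4% to 24% for Hox genes and from 7.69% to 34.6% for disc genes. On all arms but chromosome 4 it rose from 35.8% to 48.5% of genes. The absence of a summit at some of these genes can thus be a missed peak. The pair-rule gene hry (hairy) had a summit inside the gene in replicate 4 and a percentile of 33.2 ± 15.01 (SD, n = 4). The gene exd, a cofactor of Hox proteins, stood at 49.2 ± 9.57 with its strongest replicate 4 summit inside CG8939. It also had a summit inside the gene itself in at least 3 replicates. Abd-B, the most posterior Hox gene, and ara had no summit.

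For 8 lists the share did not pass the threshold. Glycolysis had 9 of 12 genes marked, led by Pgi (82.1 ± 15.9), and replication and cell cycle had 19 of 30, led by the kinase gene aurB (86.9 ± 6.91), each with an adjusted p = 0.0513 (Fisher's exact test). Over 14 other settings glycolysis passed in 3 and replication in 5. Both lists passed without fly replicate 1, at adjusted p = 0.0215 and 0.00719, and without fly replicate 2, at 0.0214 and 0.00487 (Fisher's exact test). There a summit in at least 2 of the remaining replicates was enough, so the rule was looser too. Both also passed with a summit in at least 2 of all 4 replicates (adjusted p = 0.0213 and 0.00730, Fisher's exact test). Without fly replicate 3 or 4 neither passed (adjusted p = 0.0539 and 0.0521 for each list, Fisher's exact test). The other 6 were glial genes with 1 of 10 (vkg, 65.3 ± 21.1), hemocyte genes with 2 of 12 (crq, 75.1 ± 15.3), ecdysone response genes with 6 of 21 (br, 83.5 ± 9.06), clock genes with 3 of 11 (dco, 63.6 ± 28.2), fat body genes with 4 of 13 (bmm, 89.04 ± 9.72) and heat shock genes with 8 of 21 (DnaJ-1, 73.0 ± 25.3). The strongest replicate 4 summit of each named gene except crq lay inside another gene, that of vkg inside SelT. Of these genes, Pgi, DnaJ-1 and dco also had a summit inside the gene itself in at least 3 replicates. Whether vkg belongs to glia was not checked here, so its place in the glial list is uncertain. As less often marked, glial genes passed in 3 of these settings, among them a window of 500 bp (adjusted p = 0.0235, Fisher's exact test), and ecdysone response genes in 1, when a summit in all 4 replicates was asked for (adjusted p = 0.0284, Fisher's exact test).

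The 2 directions also differed in where the summit lay. Among marked members of the 7 lists above other genes, 276 of 315 had a summit inside the gene in at least 3 replicates, against 6 of 38 in the 16 lists below. Of all 6107 marked genes 4329 had one, and the difference between the lists was not tested. Genes of a list that share a summit are not independent, so the p-values of lists with clustered genes are too small. Among isolated genes, of which 6.65% were marked, 9 lists could be tested, and only the cytoplasmic ribosomal proteins passed (adjusted p = 6.15e-05, Fisher's exact test). The same list lost its call with a window of 250 bp (adjusted p = 0.156, Fisher's exact test), and of the same 14 settings the tracheal list lost its call in 8, phototransduction in 3, the chorion and antimicrobial lists in 2 each and muscle in 1.

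**Figure D2:**
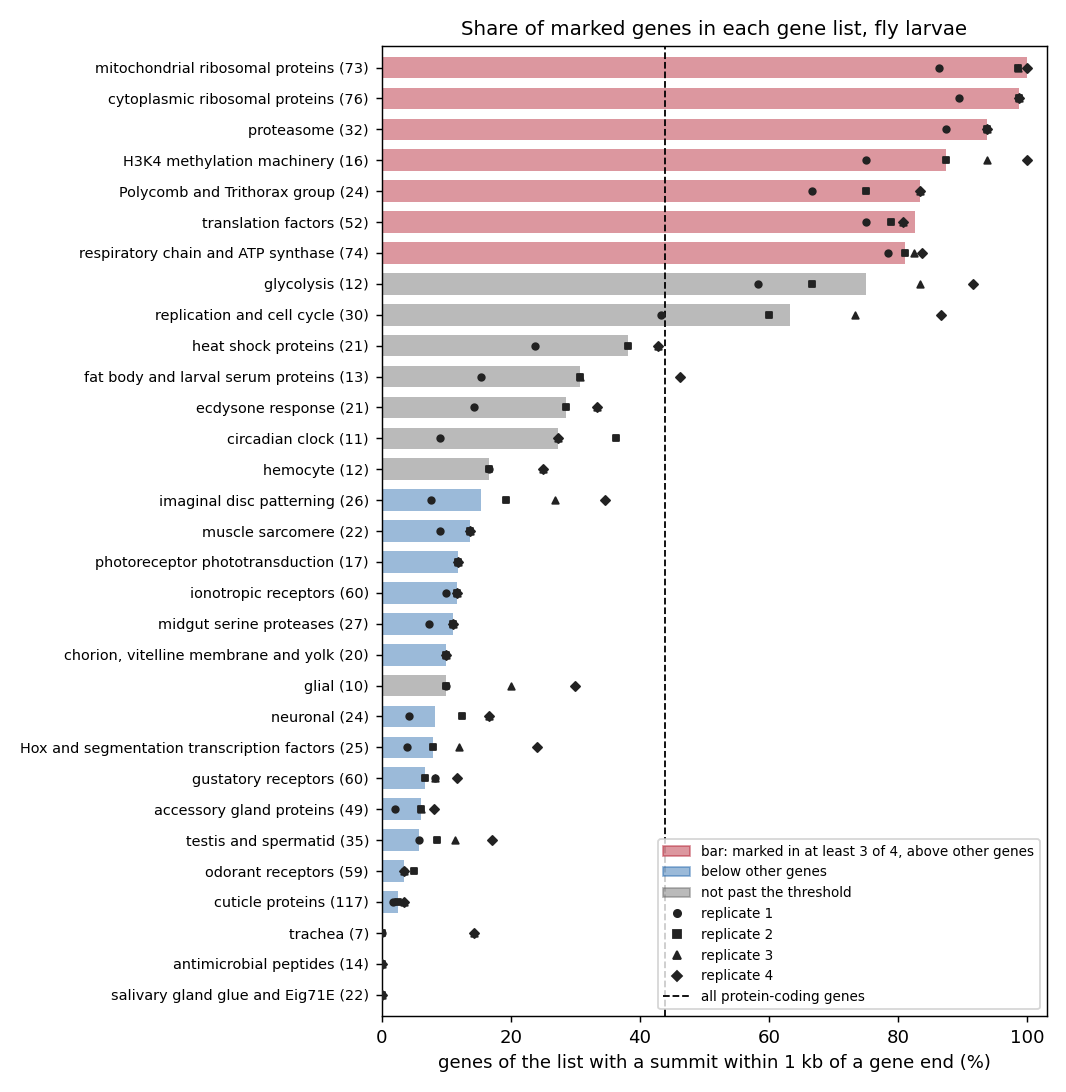
Share of protein-coding genes with a summit within 1 kb of a gene end for each gene list in fly larvae (bars, marked in at least 3 of 4 replicates; points, each replicate; number of genes in brackets; dashed line, all protein-coding genes). All 73 mitochondrial ribosomal genes are marked, and 3 of 117 cuticle genes.

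The marked genes were spread over the 6 arms that hold most fly genes. Every fly summit lay on these arms except 1 of replicate 3, on a sequence that was not identified. Genes on Y were not searched for summits. With at most that 1 summit off the 6 arms, none of the 24 protein-coding genes on Y could be marked in at least 3 replicates. The test against 43.9% elsewhere (adjusted p = 7.36e-06, Fisher's exact test) was therefore fixed by the search. Its call was lost among isolated genes (adjusted p = 0.559, Fisher's exact test), and the sex of the larvae is not given in the sources used here. Arm 2L had 41.1% of its genes marked, against 44.4% on the others (adjusted p = 0.0066, Fisher's exact test), with 40.7% ± 4.85 per replicate (SD, n = 4). Neighbouring genes of an arm that share a summit are not independent, so the p-values of all arms are likely too small. The small, largely heterochromatic chromosome 4 had 43 of 80 genes marked, 53.8% against 43.7%, which did not pass (adjusted p = 0.144, Fisher's exact test), and its share was 27.5% in replicate 1 and 55.0% to 57.5% in the other replicates. Arms X (45.2%), 2R (44.6%), 3L (42.4%) and 3R (45.5%) did not pass either, but over 12 other settings 3R passed in 8, always above the other arms, 2R in 2, X in 3 above and 3 below, and 3L in 0. The call for 2L was lost with scores of at least 5 (adjusted p = 0.114, Fisher's exact test), with equal numbers of summits (0.395), with a summit in all 4 replicates (0.0665) and among isolated genes (0.657). Among isolated genes, chromosome 4 passed at 30.2 percentage points above the other arms (adjusted p = 0.000141, Fisher's exact test) and 2R at 7.96 above (adjusted p = 1.18e-05, Fisher's exact test). X was 3.14 percentage points above the others with a summit in at least 2 replicates (adjusted p = 0.0161, Fisher's exact test), and its difference was −3.59 with equal numbers of summits (adjusted p = 0.00463, Fisher's exact test) and −4.97 among isolated genes (adjusted p = 0.000723, Fisher's exact test).

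**Figure D3:**
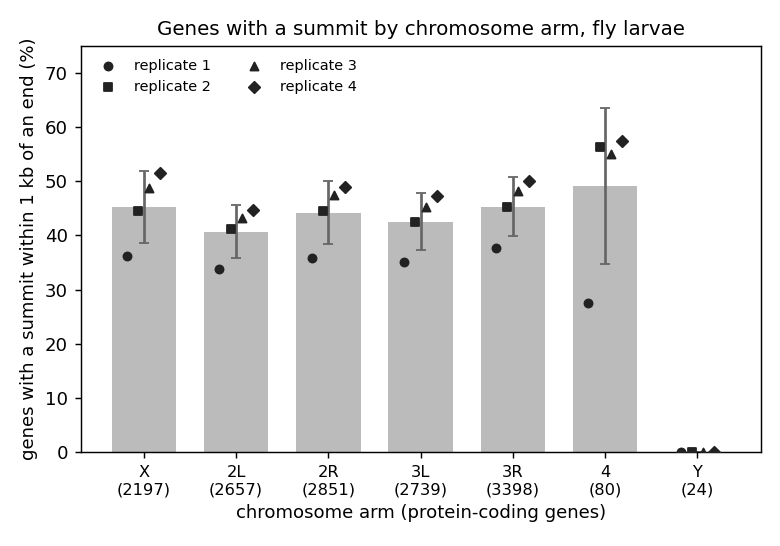
Share of protein-coding genes with a summit within 1 kb of an end on each chromosome arm (bars, mean of 4 fly replicates; error bars, SD; points, replicates; number of genes in brackets). Chromosome 4 stands at 27.5% in replicate 1 and at 55.0% to 57.5% in the others. Y stands at 0 because its genes were not searched for summits.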

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

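The tests of whether fly replicate 1 holds other regions than the rest, of chance placement of the beetle site, of its narrow span and of chromosome 4 by regions were chosen after the values had been seen. Over 41 groups of 4 replicate values, 8 held a value that stood apart from the other 3 by Dixon's criterion, the gap to the nearest value over the range. Chance gives about 5% of groups for continuous values, but in 6 of the 8 the other 3 replicates tied, sometimes 1 gene away, so that rate does not hold for these shares.

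Fly replicate 1 stood low in 7 of these. Its share of genes with a summit was 86.3% for mitochondrial ribosomal proteins, where the others had 98.6% to 100%. It was 89.5% for cytoplasmic ribosomal proteins (98.7% in the others) and 87.5% for the proteasome (93.8%). It was 10.0% for ionotropic receptors (11.7%), 7.41% for midgut serine proteases (11.1%), 9.09% for muscle sarcomere genes (13.6%) and 27.5% for chromosome 4 genes (55.0% to 57.5%). In the odorant receptors, replicate 2 stood high at 5.08%, with 3.39% in each of the others.

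The first pattern is the smaller number of summits in fly replicate 1. If this list held other regions than the rest, fewer of its summits should recur: set against as many of the highest summits of each other replicate, its share found in the same target differed by −8.58 to −7.31 percentage points (mean −7.82), between the bounds set for and against. All summits of replicate 1, weak ones included, were set against only the highest of the others, which recur more often than their full lists. A lower share can come from that alone, so this stays open. If it held the stronger part of one set of regions, those it lacks should score lower. In replicate 4 the 1179 regions present in replicates 2, 3 and 4 but absent from replicate 1 had a median percentile −17.6 points from that of the 2433 regions in all 4. The 95% interval of −20.5 to −14.9 came from resampling regions of replicate 4, which are not independent, and does not measure the spread between replicates. The difference was −13.4 in replicate 2 and −19.8 in replicate 3, so in each the regions missing from replicate 1 scored lower. Regions missing from any 1 replicate may score lower in the others, and those missing from replicates 2, 3 or 4 were not compared. The test therefore cannot tell whether this is particular to replicate 1. A lower depth or enrichment in that library stays open too, since depth is unknown. No biological explanation was tested because the larvae of the 4 replicates carry the same labels.

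The second pattern is the low share of chromosome 4 genes in fly replicate 1. With replicates 2, 3 and 4 held to their 3518 highest summits, the share was 37.5%, 42.5% and 47.5%, between the bounds set for and against a loss of weak summits, so this explanation may hold in part. For a chance loss of a few genes, 21 of 42 chromosome 4 genes with a summit in replicates 2, 3 and 4 had one in replicate 1, against 80.1% elsewhere (Fisher's exact test, p = 1.42e-05). The bound written for this test was wrong because genes share summits: by regions, 19 of 35 were kept, 54.3% against 67.5% (Fisher's exact test, p = 0.105). Chromosome 4 summits had a median score percentile of 44.1, 33.9 and 22.4 in replicates 2, 3 and 4, against 50.1 to 50.2 elsewhere. Lower scores go with a loss of weak summits but do not exclude chance. Loss of weak summits and chance cannot be told apart here, and no biological explanation was tested.

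The third pattern is the beetle site found in all 4 brains. If summits fell by chance, even on only the 59365 bp up to the last summit of each scaffold, the 3 other replicates would hold a summit within 250 bp of that in replicate 1 with a probability of at most 1.80e-06. A narrow pile-up of reads, such as a repeat collapsed in the assembly or a contaminating sequence, would give a smaller spread of positions than a promoter region, and only 0.887% of 2367 fly regions with 1 summit per replicate had a span as small as 19 bp, where the fly median was 108 bp. This is consistent with a pile-up but may also come from a single strong narrow peak, since the input and the sequence of the site were not analysed here. A difference between beetle brain and fly larvae in the mark itself was not tested.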

How the results depend on the processing

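The searches of the whole gene, of summits inside the gene and of length-matched lists were chosen after seeing the data. The share of summits near gene ends was 97.7% with equal numbers of summits, and 60.3%, 86.5% and 97.3% with windows of 250 bp, 500 bp and 2 kb. The score ratio was 1.20 with equal numbers. Sharing between replicates was 56.9%, 79.8% and 86.9% at 100, 500 and 1000 bp, and 2433 regions were in all 4 replicates. A window of 250 bp gave 2628 marked genes and 5 arms past the threshold, and leaving out 1 fly replicate gave 2 to 4 arms, with Y counted each time. Leaving out a replicate also loosened the rule to a summit in at least 2 of those left. The changes with window, distance and number of replicates follow from the width or number asked for. Equal numbers were reached by keeping only the highest summits of each replicate. Summits away from gene ends had the lower median score in every fly replicate (7.69 against 25.9 near ends in replicate 4). The higher share near ends and the lower score ratio thus follow at least in part from the cut. Any other cause of these changes, and the cause of those of the arms, was not tested. The species difference was 4757 summits with the replicate block (exact permutation p = 0.125, the smallest possible), although the replicate numbers do not pair the species, and 4573 to 5171 without 1 library (exact permutation p = 0.0571, the smallest possible), where fewer samples are the cause.

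Of the 7 lists above and 16 below other genes, 5 and 11 kept their call in all 14 alternatives that tested all 31 lists and could change a call, which leaves out the distances for shared summits. Among the 1865 isolated genes, 1 list was above and 0 below, of 9 testable; with 6.65% marked, a list has little room below. Glycolysis (−10.6 percentage points) and replication (−5.56) changed direction with a window of 250 bp, neither past the threshold. Arm X was −0.0820 with scores of at least 5, −3.59 with equal numbers, −0.449 in all 4 replicates, −2.76 at 250 bp and −4.97 among isolated genes. Arm 4 was −7.44 in all 4 replicates and −3.87 at 250 bp, neither past the threshold, and 30.2 among isolated genes, past it. At 250 bp and among isolated genes, 3L was 0.493 and 0.0810, and 3R among isolated genes was −2.87. The cause was not tested. Of the single lists and arms over all settings, 457 values kept direction and side of the threshold, 32 lost their call in the same direction, 26 gained one in the same direction and 12 changed direction, of which 3, all of arm X, passed. Distances to the most upstream start and promoter motifs were not run, for want of strand and sequence. Unknown depth limits the absence of a summit: it can be a missed peak.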

Other observations

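The search of symbol families, the paralogs and the regions inside genes were chosen after the main results had been seen.

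Beyond the fixed lists, several families of basic cell machinery were marked almost throughout. Of 67 families of at least 10 genes that share a symbol stem, 44 held no gene of a fixed list, and of these 18 were marked more often than other genes, 16 less often and 10 did not pass. All 27 Vps genes of endosomal and vacuolar sorting were marked (adjusted p = 2.06e-09, Fisher's exact test), as were 29 of 30 Polr genes of the RNA polymerases (adjusted p = 5.20e-09, Fisher's exact test). All 19 Sec genes of secretion, 20 of 21 Nup genes of the nuclear pore, 23 of 25 MED genes of Mediator and all 15 Usp genes of ubiquitin removal were marked too. Other basic families did not pass, among them Vha with 12 of 22 genes marked, Tim with 6 of 11, Klp with 7 of 11 and Pgant with 6 of 10. At the other end stood 0 of 25 Osi genes (adjusted p = 2.71e-06, Fisher's exact test), 6 of 51 Obp genes of odorant-binding proteins, 3 of 35 Ugt and 13 of 85 Cyp genes of detoxification, and 1 of 21 dpr genes of neuronal surface proteins. Histone genes had 4 of 115 marked, but most lie in near-identical repeated copies and the treatment of reads that match several of them is not given in the sources used here, so this count is uncertain.

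Within the respiratory list, the unmarked genes were mostly paralogs named after another subunit. Of 11 such paralogs, among them ND-51L1, ND-51L2, UQCR-14L and ATPsynGL, 1 was marked (ATPsynbetaL), against 59 of the 63 other genes, 93.7%. The split was drawn from the same genes, so no test is given.

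Of the 4226 repeated regions, 106 lay more than 1 kb from the ends of all protein-coding genes, and 98 of these were inside a gene. The highest mean score percentiles, with absence as 0, were at Pex19 (2L, positions 12093938 to 12093988, 93.6 ± 4.22), Doa (3R, 28889253 to 28889386, 86.5 ± 10.7) and ND-49 (chromosome 4, 570249 to 570585, 78.0 ± 25.1; SD, n = 4). EcR and Eip75B, a receptor and an early gene of the ecdysone response that had no summit near an end, each held 1 such region. Internal transcription starts were not tested, since transcripts were not used here.

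Isolated genes were marked in 6.65% of 1865 cases and other protein-coding genes in 49.6% of 12057, but a gene with close neighbours can be marked through their summits, which raises the second share by construction. With a summit inside the gene, the shares were 6.38% and 34.9%, and overlapping genes still share summits there. With genes in 10 equal classes of length, the share was 17.9% in the shortest, 56.4% in the seventh and 31.5% in the longest. A hypothesis from the strongest sites was that summits serving several genes score higher. Summits within 1 kb of at least 2 protein-coding genes had a median score percentile 11.5 points above that of summits near 1 gene (range 8.88 to 17.3, higher in 4 of 4 fly replicates). This is consistent with the hypothesis but may also come from how densely the genes in active parts of the genome lie.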
